A study of Mus musculus with 14 samples.

How the data were processed

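The series describes bulk RNA from mouse hepatocellular carcinomas of C57BL/6 animals. Per the series text, tumours arose after hydrodynamic tail-vein injection of transposon plasmids together with SB100, a Sleeping Beauty transposase that inserts them into hepatocyte genomes. One driver plasmid carried MYC and luciferase (Luc); the other carried the same cassette plus the OVA, SIN and SIY antigens (LucOS). Each model was combined with a plasmid for Aoah, the enzyme acyloxyacyl hydrolase, or with the empty vector. The series text also lists a plasmid for N-terminally truncated beta-catenin, without saying which tumours received it. The labels carry a protocol for anti-PD1 treatment, and nothing in them says that any of these tumours was treated. The labels number the tumours but do not say that each came from a separate animal, so every p-value measures only the spread between these samples. Groups were taken from the labels: 4 Luc tumours with Aoah, 4 Luc tumours with vector, 3 LucOS tumours with Aoah and 3 LucOS tumours with vector.

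Per the labels, RNA was extracted with TRIzol, mRNA was captured on poly-T beads and cDNA was primed with random hexamers. The protocol names both directional and non-directional libraries and not which was made, so a gene and an overlapping or antisense partner may share reads. The submitters' processing notes name RSEM, DESeq2 and build mm39 without versions; the aligner is not given in the sources used here. The deposited expression table holds log2 values of TPM plus a pseudocount of 1 for 29923 gene symbols in 14 samples. TPM keeps no depth, so the depth per sample is unknown and no interval or detection limit could be given from it. The authors' 2 deposited tables of their own comparisons hold log2 fold changes, Wald statistics used here as a score, and p-values for Ensembl identifiers; which group is the numerator was not stated and was read from the sign of Aoah. GENCODE M21, on the older build GRCm38, was used only to name those identifiers and to class genes, and it named 95.5% of 28026 identifiers in the Luc table and 95.6% of 26939 in the LucOS table. A further deposited table, named after the repertoire tool MiXCR, holds 20 receptor measures per tumour. Its numbers are not scaled to depth, the content of its IGL column was not stated, and the entropy and clonality of TRA were empty for Luc vector 2. No total count per gene was held, so a test on counts was not run.

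Expression was tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1). Genes were kept at 1 TPM or more in at least 3 samples, which left 13466. One mean per group was fitted over all 14 tumours, with moderated variances that followed the expression trend and were robust to unusual genes, and p-values were adjusted with the Benjamini-Hochberg method at 0.05. Adjusted p-values in the text are from this limma fit unless another test is named. The contrasts were Aoah against vector in each model, the difference between these effects (interaction), and LucOS against Luc among vector tumours and among Aoah tumours. Changes on this scale understate the change of genes at low TPM.

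Altogether 55 gene lists of cell types and pathways were written before the data were examined. The contrasts, their limma, camera, fry and repertoire tests and the rule for named genes were also set by then. The list tests by antigen in Aoah tumours and the repertoire test by antigen in vector tumours were not in that plan. Lists with at least 5 measured genes, 48 of them, were tested with camera in limma, which compares a list with all other genes, at a preset correlation of 0.01. Camera was repeated with correlations estimated from the data, which ran from 0.160 to 0.894, and fry, which tests a list without reference to other genes, was run beside it. Within a list, members were counted after adjustment over all genes and also adjusted over the list alone. The named genes were Aoah and, per Aoah contrast and for the antigen contrast in vector tumours, the 10 largest rises and 10 largest falls past 0.05. Where none passed, the 5 genes with the smallest p per direction were taken, and the interaction took up to 5 per direction. Predicted genes and receptor segments were left out of that rule. For each list, up to 4 members with the smallest p were added; some of these genes are not reported here. Repertoire measures were compared with two-sided exact permutation tests, within each model and over both models with labels permuted inside each model.

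The fit was tested on simulated data with 200 genes changed. Noise was drawn separately for each gene, unlike the correlated genes measured here, so the shares recovered may not carry over. In the Luc comparison the fit recovered 50.0% of genes changed 2-fold, 90.9% changed 4-fold and 97.0% changed 8-fold. In LucOS these shares were 30.5%, 84.4% and 86.7%, and for the interaction 15.2%, 44.9% and 74.6%. Among vector tumours the antigen contrast recovered 28.0%, 82.5% and 94.0%, and among Aoah tumours 34.3%, 84.2% and 90.4%. Alternatives covered a pseudocount of 0.1, no filter, a filter at 5 TPM, median-of-ratios and quantile scaling, only the groups compared, array weights, plain moderated variances, a block for the replicate number and each tumour left out in turn. Leaving out both Luc vector tumours above 10 TPM for Aoah, and leaving out both Aoah tumours numbered 3, were added after the data were seen. Repertoire tests and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.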

Results

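To characterise the transcriptional effect of Aoah overexpression in MYC-driven mouse liver tumours, bulk polyA RNA was profiled in 14 tumours of 4 groups. By the plasmids given, Luc tumours were to express MYC and luciferase, and LucOS tumours in addition the OVA, SIN and SIY antigens. Luciferase and the antigens were not measured. Mouse Myc stood at 0.93 to 4.1 TPM in the 14 tumours. Whether reads of the plasmid MYC would be assigned to mouse Myc is not given in the sources used here. Ctnnb1, the gene of beta-catenin, stood at 128.84 to 260.48 TPM in Luc Aoah and 198.41 to 362.8 TPM in Luc vector tumours. In LucOS it stood at 187.38 to 213.45 TPM with Aoah and 184.01 to 287.65 TPM with vector. Whether the beta-catenin plasmid contributed to these levels was not tested. Each model was combined with Aoah (4 Luc and 3 LucOS tumours) or with an empty vector (4 Luc and 3 LucOS tumours). The depth of the libraries is unknown, because the values are TPM. Between 11478 and 12836 genes reached 1 TPM per tumour, and tumours of one group correlated with each other at r = 0.906 to 0.982 across genes. In 2 tumours the composition stood apart. Small noncoding RNA of 89 genes made up 3.57% of TPM in Luc Aoah 3 against 0.0249% to 0.0713% elsewhere, with Rn7sk at 1777 TPM and Rmrp at 811 TPM there. Mitochondrially encoded genes made up 16.6% of TPM in LucOS Aoah 3 against 3.41% to 8.45% elsewhere.

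Aoah, the lipase that removes acyl chains from bacterial lipopolysaccharide, was examined first because it was the gene delivered. It stood at 498 ± 165 TPM (SD, n = 4) in Luc Aoah tumours and at 18.7 ± 25.4 TPM (SD, n = 4) in Luc vector tumours. In LucOS tumours it stood at 699 ± 201 TPM (SD, n = 3) with Aoah and at 2.10 ± 1.16 TPM (SD, n = 3) with vector. The log2 change was 5.94 (SE 0.95, limma adjusted p = 0.00228) in Luc and 7.84 (SE 1.09, adjusted p = 0.0138) in LucOS, and every Aoah tumour lay above every vector tumour of its model. The effects differed by 1.90 between models, which did not pass (adjusted p = 0.510). The Luc vector tumours were not alike: vector 1 held 18.57 TPM and vector 3 held 54.76 TPM, while vector 2 and vector 4 held 0.74 and 0.89 TPM. Without vector 1 and vector 3 the Luc change was 8.04. The LucOS call was lost without LucOS Aoah 1 (7.96, adjusted p = 0.0531) or without LucOS Aoah 3 (7.62, adjusted p = 0.0591), within a range from 5.03e-06 to 0.0774 over all alternatives.

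To identify genes that responded to Aoah without the added antigens, Luc Aoah tumours were compared with Luc vector tumours. After Aoah itself, the largest rises among the genes that the rule could name were mostly in enzymes of differentiated hepatocytes. Cyp2c50, a cytochrome P450, rose from 1.07 ± 0.496 to 114 ± 46.6 TPM (SD, n = 4 each), a log2 change of 5.73 (SE 0.60, adjusted p = 7.29e-05). Its relative Cyp2c54 rose to 57.1 ± 30.5 TPM (log2 change 5.45, adjusted p = 5.82e-05), and Inmt, an indolethylamine methyltransferase, rose from 1.89 ± 0.953 to 152 ± 132 TPM (log2 change 5.44, adjusted p = 1.18e-05). The coumarin hydroxylase Cyp2a5 rose from 9.59 ± 6.07 to 401 ± 244 TPM and the sulfotransferase Sult2a8 from 4.87 ± 1.87 to 180.04 TPM. Ces3a, a carboxylesterase, rose by 5.33, Rdh16f2, a retinol dehydrogenase family member, by 4.42 and the major urinary protein gene Mup13 by 4.28 on the log2 scale. Reads of the Cyp2c, Cyp2a, Ces, Sult2a and Mup families can be shared between close copies, so the split between members is uncertain. Snord118, a small nucleolar RNA, also passed (log2 change 4.59, SE 1.04, adjusted p = 0.0138), with 371.47 TPM in Luc Aoah 3 against 15.88 to 88.38 TPM in the other Luc Aoah tumours.

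The largest fall was in Reg3b, a secreted lectin, which fell from 1679 ± 559 to 4.59 ± 4.30 TPM (SD, n = 4 each), a log2 change of -8.46 (SE 1.27, adjusted p = 0.00181). Reg3g, its neighbour in the same family, fell from 499 ± 110 to 3.69 ± 2.41 TPM (log2 change -6.87). The protease inhibitors A2m and Serpina3n changed by -4.72 and -3.34, and Socs3, a feedback inhibitor of cytokine signalling, changed by -2.85 (SE 0.34, adjusted p = 0.000151). Gpc3, a glypican of hepatocellular carcinoma, fell from 296 ± 69.2 to 24.6 ± 19.1 TPM (log2 change -3.88, adjusted p = 0.000620), and Dlk1, an imprinted gene of fetal liver, fell from 162 ± 48.1 to 27.0 ± 23.1 TPM (log2 change -3.02). Scara5, Akr1b7 and Ier3 changed by -3.20, -3.18 and -2.91. For all 20 genes, which were selected for their change, the 4 Aoah tumours lay on one side of the 4 vector tumours; for an unselected gene the exact permutation p of that separation is 0.0286. Without vector 1 and vector 3, the pair with raised Aoah, A2m (adjusted p = 0.0663), Dlk1 (adjusted p = 0.157) and Snord118 (adjusted p = 0.135) no longer passed, each the highest value over all alternatives tried; the lowest were 3.92e-05, 0.00491 and 0.00147. Their changes without that pair were -4.58, -2.72 and 4.25, and fewer tumours entered the fit.

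In all, 2988 of 13466 genes passed in Luc tumours, 1068 higher and 1920 lower with Aoah. The median of all genes was shifted by -0.24, and values relative to it are given for some gene groups. The number and the balance of directions depended on single tumours. The share higher with Aoah was 35.7% of 2988 genes. It was 47.2% of 1393 without Luc Aoah 1, 22.9% of 5251 without Luc Aoah 2, 62.6% of 1160 without Luc Aoah 3 and 60.8% of 855 without Luc Aoah 4. It was 52.2% of 1262 without vector 1, 24.5% of 4426 without vector 2, 60.3% of 973 without vector 3 and 60.2% of 1142 without vector 4. With the replicate number as a block it was 70.6% of 618, and without vector 1 and vector 3 together 74.6% of 355, so the excess of falls did not hold throughout. Of the 48 gene lists tested with camera at the preset correlation, 18 were higher and 3 lower, and with an estimated correlation none passed (lowest adjusted p = 0.501). At the preset correlation 19 of the 21 were called with each of the 8 tumours left out in turn. Fry called 7 lists.

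**Figure D1:**
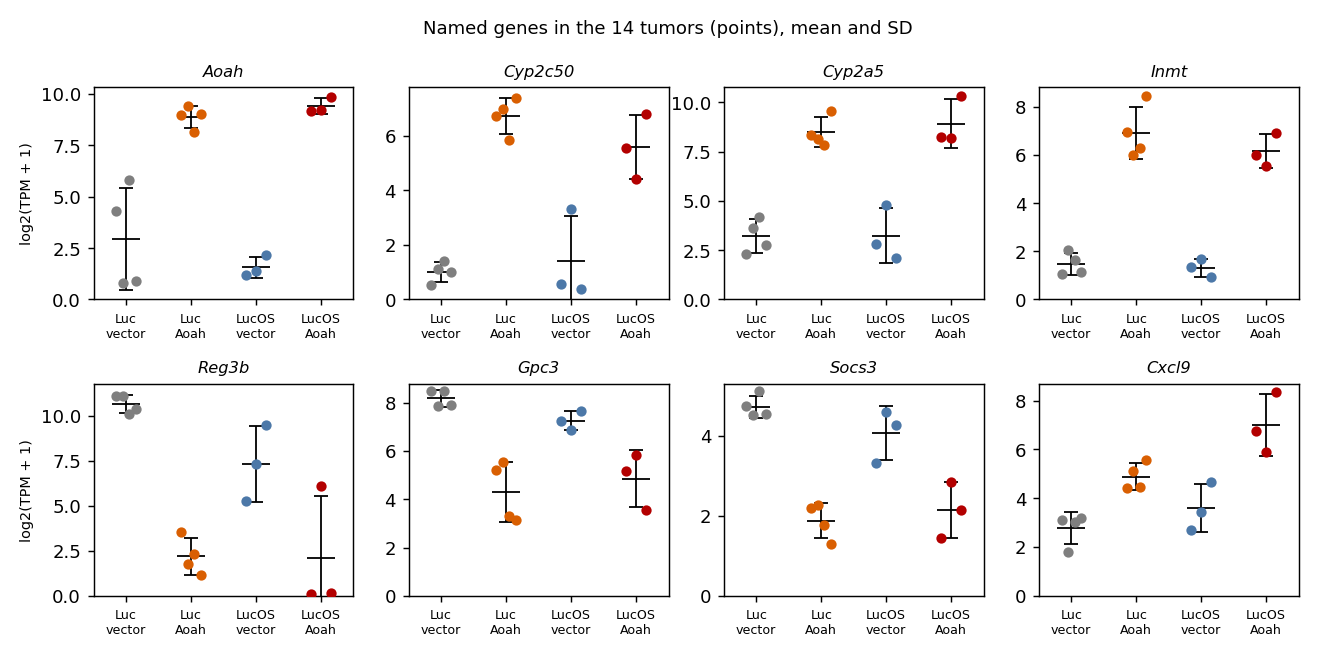
Log2(TPM + 1) of 8 named genes in each tumour (points) of the 4 groups, with the group mean and SD; bars that would run below 0 end at the axis. Cyp2c50, Cyp2a5 and Inmt were higher in every Aoah tumour than in every vector tumour of the same model, and Socs3 was lower.

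Liver metabolism genes of several lists were higher with Aoah in Luc tumours. Of 24 xenobiotic and drug metabolism genes 13 rose and none fell (14 and none adjusted over the list alone), with a median of 1.21, or 1.46 relative to all genes (camera adjusted p = 1.66e-10, adjusted p = 0.733 with an estimated correlation). Among them Ugt2b1, a glucuronosyltransferase, rose from 2.64 ± 0.703 to 40.9 ± 16.1 TPM (SD, n = 4 each). Of 20 hepatocyte genes 6 rose and 1 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.00299, adjusted p = 0.733 with an estimated correlation). Mup3 rose from 69.9 ± 30.6 to 1287 ± 304 TPM and Cyp3a11 from 422 ± 141 to 2370 ± 888 TPM, whereas the fibrinogen gene Fgb fell from 2230 ± 201 to 849 ± 387 TPM. All 12 male-biased liver genes had positive changes and 6 rose (9 adjusted over the list alone), with a median of 1.52, led by Mup11 at 4.26 and Mup20 at 2.84. That list was called by camera (adjusted p = 2.63e-07, adjusted p = 0.501 with an estimated correlation) and by fry (adjusted p = 0.00623). Female-biased genes went both ways, with 3 rises and 3 falls (4 and 4 adjusted over the list alone; camera adjusted p = 0.114). Cyp2b9 rose from 0.0175 ± 0.0236 to 12.5 ± 6.41 TPM and Cyp3a16 fell from 32.0 ± 6.04 to 4.30 ± 1.86 TPM. The labels give no sex of the animals; Xist, transcribed from the inactive X chromosome of females, stood at 6.01 to 69.69 TPM in all 14 tumours.

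Bile acid and cholesterol disposal genes rose in 7 of 17 cases and fell in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.000953, adjusted p = 0.733 with an estimated correlation). Baat, which conjugates bile acids, rose from 27.0 ± 6.05 to 129 ± 29.4 TPM, and Nr0b2, a nuclear receptor that represses bile acid synthesis, fell from 23.02 ± 6.59 to 5.47 ± 2.32 TPM. In cholesterol synthesis 6 of 24 genes rose and 1 fell, unchanged over the list alone, with Msmo1 at a log2 change of 1.65 (camera adjusted p = 0.00192, adjusted p = 0.763 with an estimated correlation). The oxidative stress list of Nrf2 targets had 4 rises among 19 genes, also 4 adjusted over the list alone, led by the glutathione transferase Gsta1 at 3.97 and the quinone reductase Nqo1 at 1.86 (camera adjusted p = 0.00291, adjusted p = 0.733 with an estimated correlation). Beta-catenin targets were divided, with 5 of 16 higher and 4 lower, the same numbers adjusted over the list alone (camera adjusted p = 0.0530). The glutamate transporter Slc1a2 rose from 2.55 ± 0.976 to 22.6 ± 6.57 TPM and Oat, ornithine aminotransferase, from 84.5 ± 29.2 to 508 ± 168 TPM.

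Fetal liver and tumour markers were lower with Aoah in Luc tumours: 9 of 16 fell and none rose (11 and none adjusted over the list alone), with a median of -1.35, or -1.11 relative to all genes. Camera called the list (adjusted p = 0.000346, adjusted p = 0.733 with an estimated correlation), as did fry (adjusted p = 0.00623). Besides Gpc3, the imprinted gene Peg3 changed by -2.14, the progenitor marker Prom1 by -1.83 and the RNA-binding protein gene Igf2bp3 by -1.21. MYC targets and ribosome biogenesis genes had 9 falls among 26 (10 adjusted over the list alone), with nucleolin, Ncl, at 270 ± 152 against 697 ± 278 TPM (camera adjusted p = 0.0123, adjusted p = 0.772 with an estimated correlation). In the unfolded protein response 6 of 20 fell (11 adjusted over the list alone), among them Xbp1 at -1.34 and Asns at -1.27 (camera adjusted p = 0.0360, adjusted p = 0.763 with an estimated correlation), a call lost without Luc Aoah 2 (0.0645) or Luc vector 1 (0.0585). Of 28 cell cycle genes none passed, also none over the list alone; the median was -0.11 and the camera direction was up (adjusted p = 0.342). The smallest p there belonged to Ccne1 at -0.87 (adjusted p = 0.0503). Acute phase genes fell in 8 of 20 cases, also 8 adjusted over the list alone, including Fga at -1.63, without a call for the list (camera adjusted p = 0.0777).

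Markers of T cells rose in Luc tumours. Of 13 T cell genes 10 rose and none fell (11 and none adjusted over the list alone), with a median of 1.39, or 1.63 relative to all genes (camera adjusted p = 4.35e-10, adjusted p = 0.501 with an estimated correlation; fry adjusted p = 0.00623). The receptor constant gene Trbc2 rose from 4.12 ± 1.62 to 25.02 ± 7.40 TPM and Cd3d, a chain of the receptor complex, from 0.838 ± 0.356 to 8.53 ± 3.08 TPM (SD, n = 4 each). Among CD8 T cell and cytotoxicity genes 11 of 13 rose (12 adjusted over the list alone), with a median of 1.74 (camera adjusted p = 1.66e-10, adjusted p = 0.501 with an estimated correlation; fry adjusted p = 0.00623). The granzyme gene Gzma rose from 4.04 ± 2.31 to 30.1 ± 10.5 TPM, Gzmb by 2.21, and the lectin receptor genes Klrd1 and Klrc1 by 2.28 and 1.87 on the log2 scale. Of 10 exhaustion genes only Cd160 rose (log2 change 1.12), 1 also adjusted over the list alone (camera adjusted p = 0.0415, adjusted p = 0.733 with an estimated correlation). The call was lost without Luc Aoah 4 (0.0839) or without Luc vector 1 (0.0519), 2 (0.0536) or 4 (0.0853). Plasma cell genes had 3 rises and 1 fall among 12 (5 and 1 adjusted over the list alone), with Jchain at 70.3 ± 29.8 against 11.7 ± 10.5 TPM and the fall in Xbp1 (camera adjusted p = 0.0196, adjusted p = 0.733 with an estimated correlation).

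Interferon gamma response genes had positive changes in all 18 cases and 8 rose (11 adjusted over the list alone), with a median of 1.28 (camera adjusted p = 1.51e-06, adjusted p = 0.733 with an estimated correlation). The GTPase gene Tgtp1 rose from 13.6 ± 2.54 to 62.9 ± 35.6 TPM and the chemokine gene Cxcl9 from 6.32 ± 2.59 to 30.4 ± 12.6 TPM. Of 20 type I interferon genes 8 rose, also 8 adjusted over the list alone, with Zbp1, a nucleic acid sensor, at 13.5 ± 1.95 against 2.80 ± 0.459 TPM (camera adjusted p = 2.3e-05, adjusted p = 0.733 with an estimated correlation). In MHC class I presentation 4 of 18 rose, also 4 over the list alone, led by the immunoproteasome gene Psmb9 at 1.99 (camera adjusted p = 0.000342, adjusted p = 0.733 with an estimated correlation). In MHC class II 2 of 10 rose, also 2 over the list alone, H2-Aa at 1.99 and H2-Ab1 at 1.30 (camera adjusted p = 0.000906, adjusted p = 0.733 with an estimated correlation). Chemokine genes had 6 rises and 2 falls among 19 (10 and 2 adjusted over the list alone), with Ccl5 at 1.77 and the neutrophil attractant Cxcl1 at -1.82 (camera adjusted p = 0.000463, adjusted p = 0.733 with an estimated correlation).

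Neutrophil genes moved the other way: 6 of 12 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -1.12. Lcn2, the iron-siderophore binder lipocalin 2, fell from 1271 ± 519 to 248 ± 230 TPM and the alarmin gene S100a8 from 106 ± 57.5 to 32.8 ± 11.1 TPM. Lcn2 is also counted among the interleukin-6 and Stat3 targets tested further below, so its fall need not mean fewer neutrophils. Camera did not call the list (adjusted p = 0.0554) and fry did (adjusted p = 0.0195). In the list for lipopolysaccharide sensing and NF-kB 6 of 18 fell (7 adjusted over the list alone), with the co-receptor gene Cd14 at -2.28 and the binding protein gene Lbp at -2.01. Its only rise was Aoah itself (3 rises adjusted over the list alone), and the list was not called (camera adjusted p = 0.311). Kupffer cell genes rose in 4 of 12 cases, also 4 adjusted over the list alone, with Clec4f at 44.2 ± 9.08 against 12.0 ± 9.48 TPM (camera adjusted p = 0.000121, adjusted p = 0.733 with an estimated correlation). Of 14 stellate cell and fibroblast genes 8 rose (9 adjusted over the list alone), with Tagln at 1.87 and the collagen gene Col3a1 at 1.74 (camera adjusted p = 4.7e-06, adjusted p = 0.572 with an estimated correlation; fry adjusted p = 0.0122). Endothelial genes rose in 4 of 13 cases, also 4 adjusted over the list alone, led by Emcn at 1.15 (camera adjusted p = 0.000676, adjusted p = 0.733 with an estimated correlation). Of 5 cholangiocyte genes 2 fell (3 adjusted over the list alone), with Sox9 at 0.415 ± 0.395 against 6.56 ± 2.73 TPM; fry called this list (adjusted p = 0.0261) and camera did not (adjusted p = 0.114).

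To test the response in tumours of the antigen plasmid, LucOS Aoah tumours were compared with LucOS vector tumours. After Aoah itself, liver enzyme genes again led the rises among the genes that the rule could name. Cyp2a5 rose from 12.0 ± 12.9 to 633 ± 582 TPM (SD, n = 3 each), a log2 change of 5.70 (SE 0.76, adjusted p = 0.00822), and Inmt from 1.54 ± 0.625 to 76.3 ± 39.4 TPM (log2 change 4.84, SE 0.52, adjusted p = 0.00108). Gsta1 rose from 1.93 ± 2.27 to 74.6 ± 78.2 TPM (log2 change 4.47, adjusted p = 0.00852), and Cyp2c50, Cyp2a4, Gsta2 and Cyp2c54 rose by 4.18, 3.82, 3.81 and 3.58 on the log2 scale. The chemokine gene Cxcl9, whose product attracts T cells, rose from 13.2 ± 9.83 to 165 ± 145 TPM (log2 change 3.40, SE 0.60, adjusted p = 0.0207), and the carboxylesterase gene Ces1g rose by 3.37. The Cyp2a, Gsta and Ces genes have close copies, so their split is uncertain. The largest fall was in Dnajc12, a co-chaperone, from 138 ± 60.8 to 22.8 ± 11.3 TPM (log2 change -2.57, SE 0.38, adjusted p = 0.00969). Prom1, Socs3, Cxcl1 and Peg3 changed by -2.15, -1.92, -1.89 and -1.86, and Fgf15, a hormone of bile acid feedback, fell from 5.17 ± 1.28 to 0.480 ± 0.429 TPM. Cyp3a16, Akr1b7, Cyp3a44 and Scara5 changed by -2.21, -2.18, -2.12 and -1.99.

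In LucOS, 130 genes passed, 101 higher and 29 lower, with a median of all genes of -0.02. All 20 named genes separated the 3 Aoah from the 3 vector tumours, which chance gives in 10.0% of cases to an unselected gene, while these were selected for their change. The number was 13 without LucOS Aoah 1, 226 without LucOS Aoah 2 and 14 without LucOS Aoah 3. It was 62 without LucOS vector 1, 353 without LucOS vector 2 and 23 without LucOS vector 3. Of the named genes Cyp2a5, Inmt and Gsta1 passed with each of these tumours left out in turn; the other 17, Aoah among them, did not. Under both other scalings 37 of the 38 genes called among named genes and list members passed, Cxcl1 being the exception. Under all pseudocounts, filters, scalings and variance settings 3 of the 38 passed throughout, and with the block, array weights, only the groups compared and the added alternatives included 0 did.

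In LucOS camera called 26 lists higher and 6 lower at the preset correlation, and with an estimated correlation none passed (lowest adjusted p = 0.268). At the preset correlation 19 of the 32 were called with each of the 6 tumours left out in turn. Xenobiotic and drug metabolism genes had 5 rises among 24 (17 adjusted over the list alone), with a median of 1.61 (camera adjusted p = 5.02e-19, adjusted p = 0.268 with an estimated correlation). Interferon gamma genes were positive in all 18 cases and 3 rose (14 adjusted over the list alone), with a median of 1.96 (camera adjusted p = 9.23e-17, adjusted p = 0.268 with an estimated correlation). Besides Cxcl9, Cxcl10 rose from 11.1 ± 3.98 to 75.5 ± 61.7 TPM and Tgtp1 by 2.39. Of 13 T cell genes 3 rose (12 adjusted over the list alone), with Trbc2 at 32.7 ± 11.1 against 9.19 ± 3.80 TPM and Cd3g at 1.81 (camera adjusted p = 9.95e-13, adjusted p = 0.268 with an estimated correlation; fry adjusted p = 0.0349). The cytotoxicity list had 1 rise, Ccl5 at 2.19 (10 adjusted over the list alone; camera adjusted p = 1.85e-10, adjusted p = 0.268 with an estimated correlation). MHC class II genes were positive in all 10 cases with a median of 1.64, none past the threshold over all genes and 8 adjusted over the list alone (camera adjusted p = 6.31e-09, adjusted p = 0.273 with an estimated correlation). In MHC class I 1 of 18 rose, Psmb9 at 2.01 (4 adjusted over the list alone; camera adjusted p = 1.25e-09, adjusted p = 0.331 with an estimated correlation). LucOS Aoah 3 stood above its group here, with H2-Aa at 1102.08 against 386.5 and 311.85 TPM and Tgtp1 at 378.08 against 146.33 and 100.36 TPM. Without it the medians were 1.28 for interferon gamma, 1.22 for MHC class II, 0.59 for MHC class I, 1.05 for T cell and 0.96 for cytotoxicity genes, with camera adjusted p of at most 1.66e-06. Without LucOS vector 2 the cytotoxicity median was 0.78.

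Plasma cell genes in LucOS had a median of 2.07, with the immunoglobulin constant gene Ighg2c rising from 2.09 ± 1.42 to 41.5 ± 5.72 TPM, the only one of 12 past the threshold over all genes (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.26e-05, adjusted p = 0.268 with an estimated correlation; fry adjusted p = 0.0349). LucOS Aoah 3 overlapped the vector group in other genes of this list: Jchain stood at 16.75 TPM there against 95.58 and 79.79 TPM in LucOS Aoah 1 and 2 and 25.2 TPM in LucOS vector 1, and Igha at 14.26 against 102.93, 58 and 21.02 TPM. Stellate cell and fibroblast genes were positive in all 14 cases and the only call was Thy1, at 1.71, a gene that mouse T cells also express (7 adjusted over the list alone; camera adjusted p = 1.02e-08, adjusted p = 0.268 with an estimated correlation; fry adjusted p = 0.0349). Hepatocyte genes had a median of 1.10, with 1 rise, the thyroxine carrier gene Ttr at 1.78 (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.4e-05, adjusted p = 0.507 with an estimated correlation). Male-biased liver genes had a median of 0.95 with none past the threshold over all genes and 4 adjusted over the list alone (camera adjusted p = 8.26e-05, adjusted p = 0.331 with an estimated correlation). Without LucOS vector 1 the hepatocyte median was 0.68, and without LucOS Aoah 3 the male-biased median was 0.62, the lowest with single tumours left out. Nrf2 targets had 3 rises among 19 (7 adjusted over the list alone), Gsta1, Gsta2 and Nqo1 (camera adjusted p = 2.82e-06, adjusted p = 0.421 with an estimated correlation).

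Among the lists that were lower in LucOS, fetal liver and tumour markers had a median of -0.71 and 2 falls of 16, Prom1 and Peg3 (5 adjusted over the list alone; camera adjusted p = 0.000290, adjusted p = 0.421 with an estimated correlation). Neutrophil genes had a median of -1.10 with no call over all genes and 5 falls adjusted over the list alone (camera adjusted p = 0.000344, adjusted p = 0.268 with an estimated correlation). Acute phase genes had 1 fall, Saa3 from 1245 ± 289 to 406 ± 85.4 TPM (6 adjusted over the list alone; camera adjusted p = 1.61e-05, adjusted p = 0.507 with an estimated correlation). That call was lost without LucOS vector 2 (median -0.07, camera adjusted p = 0.0828), against a median of -1.31 without LucOS vector 1. MYC targets had a median of -0.42 (camera adjusted p = 1.21e-05, adjusted p = 0.516 with an estimated correlation) and cell cycle genes one of -0.23 (camera adjusted p = 0.0157, adjusted p = 0.733 with an estimated correlation), without a call for any member, also adjusted over the list alone. Cytosolic ribosomal protein genes were negative in all 28 cases with a median of -0.38 (camera adjusted p = 2.73e-07, adjusted p = 0.507 with an estimated correlation). Mitochondrially encoded genes were positive in all 13 cases with a median of 0.95, with mt-Atp6 at 1949 ± 718 against 884 ± 251 TPM and an adjusted p of 0.174 (camera adjusted p = 2.82e-06, adjusted p = 0.421 with an estimated correlation). That group includes LucOS Aoah 3, the tumour with 16.6% of TPM from these genes. Without it the medians were 0.56 for mitochondrially encoded genes (camera adjusted p = 0.000985), -0.12 for ribosomal protein genes (0.0445), -0.16 for MYC targets (0.0413), -0.41 for fetal genes (0.00824) and -0.06 for cell cycle genes, which were no longer called (0.417). The cell cycle call was also lost without LucOS vector 1 (0.0543) or LucOS vector 3 (0.0619). At the other end the medians were -0.65 for MYC targets and -0.40 for cell cycle genes without LucOS Aoah 1, and -0.59 for ribosomal protein genes without LucOS Aoah 2.

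**Figure D2:**
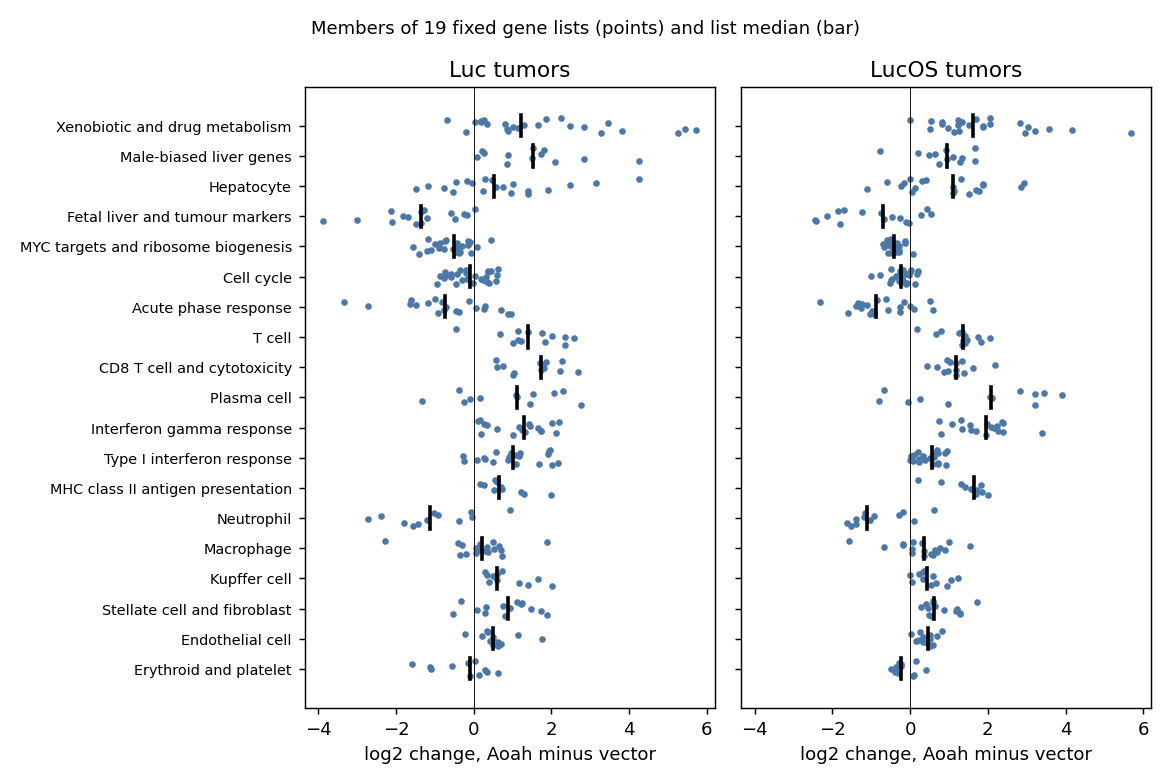
Log2 change, Aoah minus vector, of each measured member (points) of 19 gene lists and the list median (bar) in Luc tumours (left) and LucOS tumours (right). Xenobiotic metabolism had medians of 1.21 and 1.61, T cell genes 1.39 and 1.36, and neutrophil genes -1.12 and -1.10.

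The responses of both models, which share no tumour, were then compared gene by gene. Of the 130 LucOS genes 120 also passed in Luc in the same direction, 94 higher and 26 lower. By chance 8.01 and 4.13 would be shared if the calls in the models were independent. Both comparisons came from the same fit and used the same variance for each gene, so the calls are not independent. Genes of low variance can pass more readily in both, and the overlap by chance may be larger than these figures. Of the 2988 Luc genes 2518, or 84.3%, had the same sign in LucOS. Log2 changes correlated across the 13466 genes with Pearson's r = 0.55 and Spearman's rho = 0.37; genes are not independent replicates. A score made from 100 genes higher and 29 lower in LucOS lay between 2.13 and 3.20 in the Luc Aoah tumours and between -1.50 and -1.21 in the Luc vector tumours (exact permutation p = 0.0286, two-sided, n = 4 each, the smallest that this design allows).

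**Figure D3:**
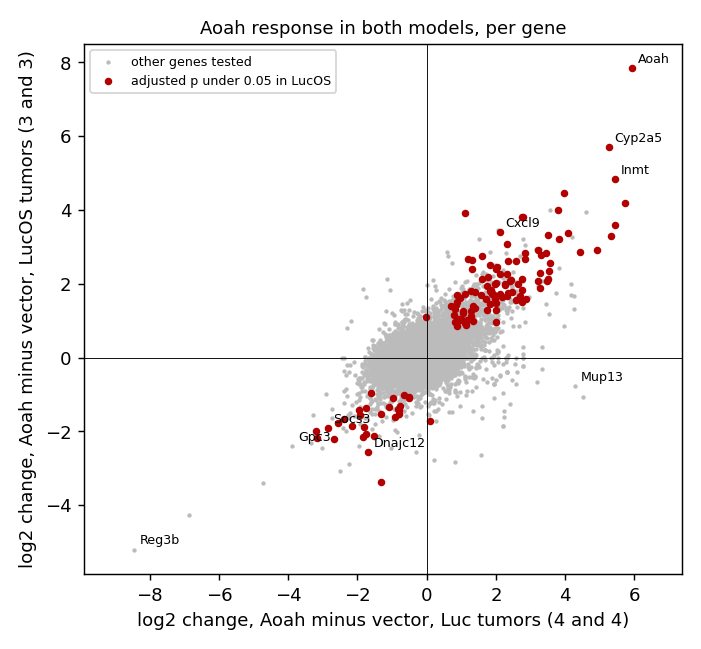
Log2 change with Aoah in Luc tumours (x axis, 4 and 4 tumours) and in LucOS tumours (y axis, 3 and 3 tumours) for every gene tested; red points have an adjusted p under 0.05 in LucOS. Cyp2a5 lay at 5.27 and 5.70 and Inmt at 5.44 and 4.84, while Mup13 lay at 4.28 and -0.76. Reads of Mup13 can be shared with close copies.

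Whether the response to Aoah differed between the models was tested with the interaction. Only Mup13 passed: it changed by 4.28 in Luc and by -0.76 in LucOS, a difference of -5.05 (SE 0.68, adjusted p = 0.0315). In LucOS it stood at 0.627 TPM with Aoah and 2.01 TPM with vector. It ceased to pass without Luc Aoah 2, 3 or 4, without any LucOS Aoah tumour, without LucOS vector 1 or 2, and without Luc vector 2 or 3, each leaving no gene; without LucOS vector 3 there were 2. Over all alternatives the adjusted p of Mup13 ran from 0.00949 to 0.713. Reads of Mup genes can be shared between close copies, so the split between them is uncertain. Summed over 22 Mup genes, the log2 change was 3.56 in Luc and 1.34 in LucOS (exact permutation p = 0.0286 and 0.1). The negative change of Mup13 in LucOS therefore does not show a fall of the family. A total of 1378 genes had an unadjusted p under 0.05. The cholangiocyte and progenitor factor Sox9 (difference 2.01), Bicc1 (1.76), Akap13 (1.85), Apoa4 (1.49) and Adcy2 (1.02) had small unadjusted p-values and did not pass (adjusted p = 0.443 each). Camera called 6 lists at the preset correlation, with adjusted p = 0.980 for each with an estimated correlation. The median difference, LucOS minus Luc, was -0.42 for type I interferon genes (adjusted p = 0.0181), -0.30 for CD8 T cell and cytotoxicity genes (0.0493), -0.11 for cell cycle genes (0.0181), -0.20 for cytosolic ribosomal protein genes (0.0342) and -0.60 for male-biased liver genes (0.00589). Mitochondrially encoded genes differed by 1.24 (adjusted p = 0.00462), again with LucOS Aoah 3 in the comparison. The median of all genes differed by 0.23. Without LucOS Aoah 3 the number of lists was 15, and without LucOS vector 3 it was 10. With each of the 14 tumours left out in turn, mitochondrially encoded genes were called in 14 fits, male-biased genes in 12, type I interferon and cell cycle genes in 11 each, ribosomal protein genes in 8 and cytotoxicity genes in 6. The median difference was lowest without LucOS Aoah 3 for type I interferon (-1.23), cytotoxicity (-0.78), male-biased (-1.10) and mitochondrially encoded genes (0.84). It was highest at -0.08 without LucOS vector 2, -0.09 without LucOS vector 3, -0.15 without LucOS Aoah 2 and 1.53 without LucOS Aoah 1, in the same order. It ran from -0.29 (without Luc Aoah 3) to 0.10 (without Luc vector 2) for cell cycle genes and from -0.37 (without LucOS Aoah 2) to 0.10 (without LucOS Aoah 3) for ribosomal protein genes.

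To describe how the models differed without Aoah, LucOS vector tumours were compared with Luc vector tumours. Model and injection or sequencing batch may not be separable. A difference here or in another comparison of LucOS with Luc therefore cannot be credited to the antigens alone. No gene passed in limma, and 1918 had an unadjusted p under 0.05. On the higher side Ifi27l2a, an interferon-induced gene, stood at 60.7 ± 41.8 TPM in LucOS (SD, n = 3) and 4.70 ± 2.19 TPM in Luc (SD, n = 4), a log2 change of 3.29 (adjusted p = 0.113). Ms4a6b stood at 24.0 ± 14.8 against 4.52 ± 1.09 TPM and Plac8, a myeloid gene, at 162 ± 101 against 48.4 ± 15.1 TPM (adjusted p = 0.212 and 0.344). Serpina7 and Selenow had log2 changes of 1.24 and 0.88 (adjusted p = 0.212 each). On the lower side Sox9 stood at 0.897 ± 0.620 against 6.56 ± 2.73 TPM (log2 change -1.97, adjusted p = 0.113) and Apoa4, an apolipoprotein gene, at 174 ± 38.0 against 486 ± 151 TPM (log2 change -1.44, adjusted p = 0.178). Aqp4, Gmpr and Adcy2 had changes of -1.42, -1.77 and -0.97. The count became 1 without LucOS vector 1 and 1 without Luc vector 1. It was 2 with only the groups compared in the fit, 4 with no filter and 3949 with array weights.

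Of the lists, camera called 13 higher and 2 lower by antigen in vector tumours, none of them with an estimated correlation (lowest adjusted p = 0.599). At the preset correlation 11 of the 15 were called with each of the 7 tumours left out in turn. The median of all genes was -0.25 here. All 20 type I interferon genes had positive changes with a median of 1.03, or 1.28 relative to all genes, none past the threshold over all genes or adjusted over the list alone (camera adjusted p = 1.13e-15, adjusted p = 0.652 with an estimated correlation). Zbp1 stood at 17.5 ± 12.2 TPM in LucOS and 2.80 ± 0.459 TPM in Luc, but LucOS vector 1 lay near the Luc level, with Zbp1 at 3.97 TPM against 20.83 and 27.62 TPM in LucOS vector 2 and 3. The same held for Isg15, at 2.6 against 35.75 and 25.95 TPM (3.16 to 4.26 TPM in Luc vector), and Ifit3, at 0.64 against 10.38 and 7.84 TPM (0.38 to 1.25 TPM). Cytotoxicity genes had a median of 0.71, none past the threshold over all genes and 4 adjusted over the list alone, with Gzma at 19.3 ± 14.6 against 4.04 ± 2.31 TPM (camera adjusted p = 2.18e-08, adjusted p = 0.652 with an estimated correlation). Neutrophil genes had a median of 0.49, none past the threshold over all genes and 3 adjusted over the list alone, with S100a8 at 349 ± 115 against 106 ± 57.5 TPM (camera adjusted p = 9.85e-06, adjusted p = 0.599 with an estimated correlation). Interferon gamma, MHC class I and II, T cell, exhaustion, chemokine, monocyte and plasmacytoid dendritic cell lists were also higher, with medians from 0.28 to 0.80 (each with adjusted p = 0.652 with an estimated correlation). The sizes rested on single tumours. Without LucOS vector 1 the medians were 1.74 for type I interferon, 0.40 for cytotoxicity, 0.90 for neutrophil, 1.08 for interferon gamma, 0.63 for MHC class I, 0.87 for MHC class II and 0.72 for monocyte genes. Without LucOS vector 2 they were 0.19 for neutrophil, 0.02 for MHC class I, 0.51 for plasmacytoid dendritic cell, 0.82 for T cell and 0.61 for chemokine genes. Without LucOS vector 3 they were 0.38 for interferon gamma, 0.16 for MHC class II, 0.07 for monocyte and 0.05 for chemokine genes, and without Luc vector 2 the T cell median was 0.27. Cell cycle genes, with a median of 0.10, and cholesterol synthesis genes, with a median of -0.01 and the test pointing up, were called too (adjusted p = 0.951 each with an estimated correlation), but not with every tumour left out. The cell cycle call was lost without Luc vector 2 (median -0.16, camera adjusted p = 0.227). The cholesterol call was lost without LucOS vector 2 (-0.42, test pointing down, 0.930), Luc vector 1 (-0.05, 0.0669) or Luc vector 2 (-0.18, 0.223), and the median was 0.25 without LucOS vector 1. Cholangiocyte genes had a median of -0.65 with 4 of 5 lower adjusted over the list alone (camera adjusted p = 0.0203, adjusted p = 0.652 with an estimated correlation), and fatty acid oxidation genes had one of -0.59 (camera adjusted p = 0.0114, adjusted p = 0.951 with an estimated correlation). Without LucOS vector 1 these medians were -0.42 and -0.31. The cholangiocyte call was lost without Luc vector 2 (0.0880), and the fatty acid oxidation call without Luc vector 1 (0.0776) or LucOS vector 3 (0.0619).

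Among Aoah tumours, LucOS and Luc differed in 11 genes, all lower in LucOS, which are named after their values were seen. Mup13 changed by -4.32 (adjusted p = 0.00303), and Car4, a membrane carbonic anhydrase, stood at 0.470 ± 0.335 TPM in LucOS (SD, n = 3) against 36.0 ± 23.4 TPM in Luc (SD, n = 4), a log2 change of -4.48 (SE 0.57, adjusted p = 0.00864). Catsperz changed by -2.61, Cox8b by -2.62, Emb by -2.36, Apela by -1.80 and Sult2a7 by -1.58; the remainder were 4 predicted or unnamed loci. Left out in turn, Luc Aoah 1 to 4 gave 10, 5, 3 and 7 genes and LucOS Aoah 1 to 3 gave 1, 2 and 10. Camera called 13 lists higher in LucOS and 2 lower, none with an estimated correlation (lowest adjusted p = 0.562). Only 5 of the 15, for interferon gamma, MHC class I, MHC class II, mitochondrially encoded and neutrophil genes, were called with each of the 7 tumours left out in turn. Interferon gamma genes had a median of 1.32, none past the threshold over all genes and 14 of 18 adjusted over the list alone, with Cxcl9 at 165 ± 145 against 30.4 ± 12.6 TPM (camera adjusted p = 2.6e-17, adjusted p = 0.562 with an estimated correlation). MHC class II genes had a median of 1.37 with 8 of 10 adjusted over the list alone (camera adjusted p = 2.41e-09, adjusted p = 0.562 with an estimated correlation), and exhaustion genes one of 0.66 with 5 of 10 adjusted over the list alone, Lag3 at 1.24 and Tigit at 1.38 (camera adjusted p = 6.5e-05, adjusted p = 0.683 with an estimated correlation). Without LucOS Aoah 3 the medians were 0.63 for interferon gamma, 0.90 for MHC class II and 0.14 for exhaustion genes, the last no longer called (camera adjusted p = 0.0560). That tumour stood highest for these genes: Cxcl9 at 329.76 TPM against 105.39 and 58.51 TPM in LucOS Aoah 1 and 2, H2-Aa at 1102.08 against 386.5 and 311.85 TPM, Lag3 at 6.64 against 1.46 and 1.4 TPM, and Tigit at 8.18 against 2.14 and 0.91 TPM. Luc Aoah tumours held at most 46.85, 245.02, 1.07 and 0.74 TPM of these genes. Mitochondrially encoded genes had a median of 1.03 (camera adjusted p = 1.78e-10, adjusted p = 0.562 with an estimated correlation), and 0.58 without LucOS Aoah 3. Male-biased liver genes and Kupffer cell genes were lower, with medians of -0.57 and -0.39 (adjusted p = 0.743 and 0.834 with an estimated correlation). Without LucOS Aoah 2 these were -0.23 and -0.22 and neither was called (camera adjusted p = 0.113 and 0.221); the Kupffer call was also lost without LucOS Aoah 1 (0.159). Without LucOS Aoah 3 they were -0.91 and -0.63.

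The deposited repertoire table was used to follow lymphocyte receptors. In Luc tumours TRB clones, the deposited measure of rearranged T cell receptor beta sequences, numbered 104 ± 25.3 with Aoah and 7.75 ± 3.86 with vector (SD, n = 4 each), and distinct TRB clonotypes 68.3 ± 13.1 and 6.5 ± 3.00. TRB entropy was 5.82 ± 0.371 against 2.52 ± 0.665 bits, and IGL clones numbered 1005 ± 282 against 246 ± 229. Of 20 measures 6 reached the smallest exact permutation p possible with 4 against 4, 0.0286, but none passed after adjustment (adjusted p = 0.0952). In LucOS TRB clones numbered 108 ± 42.3 with Aoah and 39.0 ± 28.4 with vector (SD, n = 3 each), IGL clones 972 ± 535 and 152 ± 202, and IGH clones 254 ± 149 and 34.7 ± 43.1. Distinct TRB clonotypes, 58.3 ± 12.7 and 28.3 ± 26.8, and TRB entropy, 5.396 ± 0.0607 and 4.06 ± 1.82 bits, overlapped between the LucOS groups (exact permutation p = 0.3 and 0.4). LucOS Aoah 3 stood apart in heavy chains, with 23 distinct IGH clonotypes against 299 and 137 in LucOS Aoah 1 and 2, a clonality of 0.478 and an IgG share of 96.9%. The exact permutation p could not fall below 0.1 there, and none of the 20 reached 0.05 (lowest adjusted p = 0.545). Over both models, with labels permuted inside each, 7 measures passed and 11 had an unadjusted p under 0.05. TRB clones were higher with Aoah by 82.7 and IGL clones by 789.8 on average (exact permutation p = 0.00143, the smallest possible, adjusted p = 0.0143). By antigen in vector tumours TRB clones alone had an exact permutation p of 0.0286 (adjusted p = 0.571). These numbers are not scaled to depth.

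**Figure D4:**
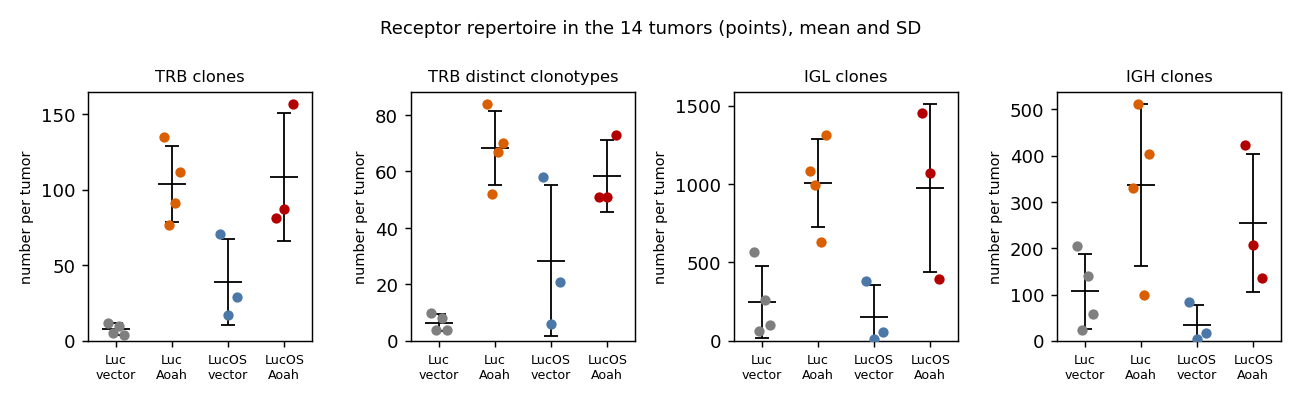
Number of TRB clones, distinct TRB clonotypes, IGL clones and IGH clones per tumour (points) in the 4 groups, with the group mean and SD. The Luc vector mean of TRB clones was 7.75 and the Luc Aoah mean was 104.

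The expression table showed receptor segments in the same direction. Of 18 measured T cell receptor segments all were positive in Luc and 13 rose, with a median of 1.11; in LucOS all 18 were positive and 1 rose, with a median of 0.61. Of 93 immunoglobulin segments all were positive in both models, with 19 rises and a median of 0.92 in Luc and 3 rises and a median of 0.93 in LucOS. By antigen in vector tumours 16 of 18 T cell receptor segments were positive, with a median of 0.44, and 9 of 93 immunoglobulin segments, with a median of -0.42. Similar segments share reads, so single segments are not named.

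The authors' own comparisons were set beside these results. In the authors' deposited table for Luc 6046 genes had an adjusted p under 0.05, 2978 higher and 3068 lower by sign, and in the authors' deposited table for LucOS 454 did, 326 higher and 128 lower. Of 2867 Luc genes called here that the authors' deposited table named, 2757, or 96.2%, passed there with the same sign; in LucOS 108 of 124, or 87.1%, did, with 0 of opposite sign in either by limma calls. Fold changes correlated across genes with the authors' deposited table at Spearman's rho = 0.98 in both models. Aoah had a log2 fold change of 5.01 in the authors' deposited table for Luc and 8.36 in that for LucOS. Cyp2c50 and Cyp2c54, called here in LucOS, had adjusted p-values of 0.0518 and 0.128 in the authors' deposited table.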

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

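Of 125 groups of 4 tumours checked for a tumour far from the others, 3 (2.4%) held one, and chance gives about 1 in 20. Akap13 stood at 2.06 TPM in Luc Aoah 2 and at 0.81 to 0.97 TPM in the other Luc Aoah tumours. Cxcl9 stood at 2.51 TPM in Luc vector 2 and at 7.03 to 8.19 TPM in the other Luc vector tumours. The IgM share of heavy-chain isotype calls was 1.27% in Luc vector 1 and 0 in the other Luc vector tumours.

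In the interaction test fixed in advance 1 gene passed and camera called 6 lists at the preset correlation, none of them with an estimated correlation (adjusted p = 0.980 each). In the splits of the tumours, a test chosen after the results were seen, 17 of 100 gave as many genes (highest other 1) and 98 of 100 as many lists (highest other 37), so chance is not excluded for either. Mup13 differed by -5.05 on the log2 scale (LucOS minus Luc, adjusted p = 0.0315) and missed the threshold in 16 of 25 fits, alternatives and single tumours left out included. The median difference was -0.30 for CD8 T cell and cytotoxicity genes (camera adjusted p = 0.0493), -0.42 for type I interferon genes (0.0181) and -0.11 for cell cycle genes (0.0181). It was -0.20 for cytosolic ribosomal protein genes (0.0342), -0.60 for male-biased liver genes (0.00589) and 1.24 for mitochondrially encoded genes (0.00462). With single tumours left out these ran from -0.78 to -0.09, -1.23 to -0.08, -0.29 to 0.10, -0.37 to 0.10, -1.10 to -0.15 and 0.84 to 1.53, with the extremes without LucOS Aoah 3 or another single tumour. With median-of-ratios scaling 2 lists were called and with quantile scaling 3.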

How the results depend on the processing

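The splits of the tumours and 2 alternatives, leaving out both Luc vector tumours above 10 TPM for Aoah or both Aoah tumours numbered 3, are tests chosen after the results were seen. With single tumours left out the medians of called lists kept their sign in 21 of 21 lists in Luc, 28 of 32 in LucOS (type I interferon reached -0.23), 4 of 6 for the interaction, and 13 of 15 by antigen in vector and in Aoah tumours each. The balance of calls in Luc turned: 35.7% were higher in the fit reported and 55.4% with no filter, 70.6% with the replicate block and 22.9% to 62.6% with single tumours left out. With no expression filter 1288 genes passed in Luc (713 higher, 575 lower), 15 in LucOS, 2 for the interaction, 4 by antigen in vector tumours and 6 by antigen in Aoah tumours; more genes were then tested. A pseudocount of 0.1 gave 0 genes for the interaction in limma (1317 unadjusted) and 4 by antigen in Aoah tumours, and a filter at 5 TPM also gave 4 there. Median-of-ratios scaling gave 239 genes in LucOS, 0 for the interaction (2160 unadjusted) and 19 by antigen in Aoah tumours, with 2 interaction lists; quantile scaling gave 256 and 27 genes and 3 interaction lists. In Luc median-of-ratios scaling moved the median of all genes from -0.24 to -0.00496 and gave 4233 genes, 45.0% of them higher. With only the groups compared in the fit, 6 genes passed in LucOS, 2 by antigen in vector tumours and 2 by antigen in Aoah tumours. Array weights gave 7339 genes in Luc, 939 in LucOS, 1144 for the interaction, 3949 and 66 by antigen in vector and Aoah tumours, and 11 interaction lists. Beyond the number of genes tested under each filter, the cause was not tested.

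With the replicate number as a block 618 genes passed in Luc, 0 in LucOS (1081 unadjusted in limma), 0 for the interaction (423) and 0 by antigen in Aoah tumours (440), and the Aoah change in LucOS of 7.84 had an adjusted p of 0.0774, the highest over the alternatives (lowest 5.03e-06). The labels do not say whether tumours of the same number were paired. Same-numbered tumours deviated from their group means with correlations from -0.554 to 0.0956. These values gave no sign of pairing but cannot exclude it. Camera with an estimated correlation called 0 lists in Luc (4 unadjusted), LucOS (8), the interaction (0) and by antigen in vector tumours (2); fry called 7, 3, 0 and 0. The 7 repertoire measures that passed over both models together compare with 0 in each model, where fewer tumours limit the smallest exact p.

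With each tumour left out in turn, 855 (without Luc Aoah 4) to 5251 (without Luc Aoah 2) genes passed in Luc and 13 (without LucOS Aoah 1) to 353 (without LucOS vector 2) in LucOS. The range was 0 to 2 for the interaction, 0 to 1 by antigen in vector tumours and 1 to 10 by antigen in Aoah tumours. The Aoah change in LucOS ran from 7.62 to 8.13, and interaction lists from 4 to 15. Without both high Luc vector tumours 355 genes passed in Luc (74.6% higher), 354 of them among the 2988, and 0 for the interaction (377 unadjusted). Without both Aoah tumours numbered 3, 1374 genes passed in Luc, 15 in LucOS, 0 for the interaction (606 unadjusted) and 5 by antigen in Aoah tumours, with 19 interaction lists and an Aoah change in LucOS of 7.62. Fewer tumours entered these fits. Of 157 genes called in Luc among named genes and list members, 148 passed under both other scalings and 103 with each tumour left out; in LucOS these were 37 and 4 of 38. Under all settings but single tumours left out, 60 of 157 and 0 of 38 passed throughout. A test on counts was not run, since no counts were held, and the interaction needs all 4 groups. Depth is unknown and its effect could not be assessed.

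Among all splits into groups of the same sizes, 2 of 35 gave at least the 2988 genes of the Luc comparison, so chance is not excluded. Exchanging Luc Aoah 2 and Luc vector 2 gave 4774, and the reason was not tested. After median-of-ratios scaling 1 of 35 splits gave at least the real count (4233, highest other 3647), the smallest share that 35 splits allow. That share does not exclude chance by itself, because another split came close behind and the split tests were not adjusted for their number. Splits were not run under the other alternatives. For genes by antigen in Aoah tumours 1 of 35 splits gave as many (11, highest other 4), again the smallest share possible. The count was 0 with the replicate block and 2 with only the groups compared, so chance is not excluded there either. Other splits gave up to 37 lists against 15, and up to 3429 genes with an unadjusted p under 0.05 against 944. In LucOS 10 splits are too few for a share under 0.05: 130 genes against a highest other of 7 (1 of 10), 239 against 12 after scaling (1 of 10) and 32 lists against 32 (2 of 10). Chance is not excluded for the interaction (1 gene, highest other 1, 17 of 100), or for lists in Luc (21, highest other 33, 10 of 35), for the interaction (6, highest other 37, 98 of 100) and by antigen in vector tumours (15, highest other 28, 24 of 35). By antigen in vector tumours 0 genes passed in limma, a count that 35 of 35 splits reach whatever the data (highest other 2), so it says nothing about chance. For the 1918 genes there with an unadjusted p under 0.05, 4 of 35 splits gave as many (highest other 5110, after exchanging LucOS vector 2 and Luc vector 2), so chance is not excluded.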

Other observations

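The tests of explanations and of the imprinted and Stat3 gene groups were chosen after the results were seen. The gene lists described first were planned, as were their tests except those by antigen in Aoah tumours. Further metabolic and stress lists were not called by camera in Luc tumours. Of 20 hypoxia and glycolysis genes 5 fell and 1 rose, the same adjusted over the list alone (median -0.44, camera adjusted p = 0.114), with the oxygen sensor gene Egln3 at 9.21 ± 2.65 TPM with Aoah against 35.1 ± 10.1 TPM with vector (SD, n = 4 each, log2 change -1.82, adjusted p = 0.000380) and the glucose transporter gene Slc2a1 at -0.89. In LucOS none of the 20 passed, also none over the list alone (camera adjusted p = 0.702). Of 14 ferroptosis genes 3 rose and 3 fell (3 and 4 adjusted over the list alone), with the median at -0.31 and the camera direction up (adjusted p = 0.865). The ferritin gene Fth1 fell from 5210 ± 479 to 2240 ± 486 TPM and the lipid peroxide reductase gene Gpx4 rose from 424 ± 68.5 to 936 ± 141 TPM. Fatty acid oxidation genes had 2 rises and 3 falls among 23 (2 and 6 adjusted over the list alone; camera adjusted p = 0.870), with the median at -0.17 and the camera direction up. The omega hydroxylase gene Cyp4a10 rose by 2.85 on the log2 scale. Thrsp, a lipogenic factor, was the only one of 19 fatty acid synthesis genes that passed in Luc, from 38.4 ± 16.4 to 223 ± 43.0 TPM, and also the only one in LucOS, from 46.5 ± 39.6 to 239 ± 48.3 TPM (SD, n = 3 each), 1 in each also adjusted over the list alone. In Luc the median of that list was -0.04 and the camera direction up (adjusted p = 0.338). Complement and coagulation genes had 3 rises and 2 falls among 26 (3 and 6 adjusted over the list alone; camera adjusted p = 0.797), with C8g at 139 ± 30.2 against 22.6 ± 5.18 TPM and C1ra at -1.16. Of 16 lipid mediator genes 2 rose, Cyp4f14 by 3.22 and the prostaglandin dehydrogenase gene Hpgd by 0.80, also 2 over the list alone (camera adjusted p = 0.110).

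Macrophage, monocyte, matrix and several other lists were not called in Luc either. Lyz2 rose from 77.6 ± 14.8 to 285 ± 39.3 TPM (SD, n = 4 each) while Cd14 fell, the only calls among 18 macrophage genes, also adjusted over the list alone (camera adjusted p = 0.0750). Of 10 monocyte genes 2 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.348), with Ly6c2 at 1.37 and Chil3 at -2.34. Extracellular matrix and TGF-beta genes had 3 rises and 3 falls among 20 (4 and 4 adjusted over the list alone; camera adjusted p = 0.259), with S100a4 at 81.5 ± 24.9 against 14.0 ± 8.37 TPM; the median was 0.02 and the mean -0.08. The p53 list had 1 rise and 3 falls among 19 (1 and 4 adjusted over the list alone; camera adjusted p = 0.865). Immediate early genes had 2 falls among 12, Ier3 and Junb, also 2 over the list alone (camera adjusted p = 0.715). Dendritic cell type 1 and type 2, plasmacytoid dendritic cell, erythroid, phospholipid remodelling, immunosuppression and nuclear respiratory chain lists were not called in Luc, with camera adjusted p from 0.0777 to 0.870. Mitochondrially encoded and cytosolic ribosomal genes were not called there either (0.958 and 0.295). In LucOS 14 further lists were called higher by camera: beta-catenin targets, bile acid disposal, cholesterol synthesis, fatty acid oxidation and synthesis, lipid mediators, chemokines, exhaustion, type I interferon, both dendritic cell types, Kupffer, endothelial and matrix genes. With an estimated correlation their adjusted p ran from 0.421 to 0.733. At the preset correlation the beta-catenin, bile acid disposal and chemokine calls held with each of the 6 tumours left out in turn, and the others did not. Without LucOS Aoah 3 the type I interferon median was -0.23 with the test pointing down (camera adjusted p = 0.293), and type 1 dendritic cell (-0.06, 0.399), lipid mediator (-0.01, 0.365), Kupffer (0.11, 0.428) and fatty acid synthesis genes (0.07, 0.111) were not called. The same tumour left out ended the calls for matrix (0.22, 0.152), type 2 dendritic cell (0.34, 0.0855), exhaustion (0.25, 0.0727) and endothelial genes (0.26, 0.0727). Without LucOS vector 1 type I interferon (-0.18, 0.914), type 1 dendritic cell (-0.05, 0.217), cholesterol synthesis (0.04, 0.205), fatty acid oxidation (0.01, 0.120), lipid mediator (0.09, 0.114) and Kupffer genes (0.33, 0.0530) were not called. Calls were also lost for both dendritic cell types without LucOS vector 2 (0.116 and 0.113). Without LucOS vector 3 those for fatty acid synthesis (0.308), fatty acid oxidation and Kupffer genes (0.121 each) were lost, and without LucOS Aoah 1 that for fatty acid oxidation (0.0779). The other 16 lists were not called in LucOS. Lists for regulatory T, NK, B and mast cells, pancreatic acinar cells, muscle, and adipocytes with mesothelium had too few measured genes to be tested.

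Liver enzyme genes rose and fetal tumour genes fell with Aoah in Luc, and in LucOS 5 of 24 xenobiotic genes rose and 2 of 16 fetal genes fell, no list being called with an estimated correlation. Reads split between near-identical copies were argued against as the whole cause, because 6 families summed over all copies still rose by a median of 1.85 on the log2 scale in Luc (1.36 for Cyp2c to 4.87 for Cyp2a, each exact permutation p = 0.0286, n = 4 each) and 1.31 in LucOS (0.866 for Cyp2c to 5.27 for Cyp2a, exact permutation p of 0.1 or 0.2, n = 3 each), though single genes such as Cyp2c50 rose further (5.73 in Luc). Non-tumour liver in the samples would lower cell cycle and fetal genes alike, if cell cycle transcripts came from tumour cells alone. Other dividing cells could not be told apart in bulk RNA. In Luc the cell cycle mean moved apart from the fetal mean by 1.33 (exact permutation p = 0.0286). On that condition the gap argues against non-tumour liver as the whole cause. It stays open as a part: Kupffer genes were positive in 12 of 12 cases and endothelial genes in 12 of 13, and Clec4g of liver sinusoids stood at 8.85 to 13.89 TPM against 1.65 to 6.24 TPM. In LucOS the gap of 0.674 (exact permutation p = 0.2, n = 3 each) leaves it open, and a more differentiated state of the tumour cells may explain the pattern in both models.

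T cell genes rose with Aoah (10 of 13 in Luc and 3 of 13 in LucOS), without a call for the list at an estimated correlation (camera adjusted p = 0.501 and 0.268). A lower share of the main cell type would raise the markers of every other type alike. The neutrophil mean instead changed by -2.51 relative to the T cell mean in Luc (exact permutation p = 0.0286, n = 4 each). This argues against a lower share as the whole cause in Luc. The same difference was -2.13 in LucOS (exact permutation p = 0.1, n = 3 each). That p is the smallest possible there, so the test could not pass, and a lower share stays open in LucOS. In Luc 8 of 14 stellate, 4 of 12 Kupffer, 4 of 13 endothelial and 3 of 12 plasma cell genes rose (1 of the last fell; no list called with an estimated correlation, adjusted p = 0.572 to 0.733), which leaves it open as a part. Blood left in the tumours was argued against in Luc by an erythroid mean that changed by -1.75 relative to the T cell mean (exact permutation p = 0.0286) and stays open in LucOS (-1.44, exact permutation p = 0.4). A larger number of T cells, or more transcripts of these genes per T cell, may explain the rise and was not tested.

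Aoah stood above 10 TPM in Luc vector 1 and vector 3. Reads carried over from the Aoah libraries would raise other genes that are high in Luc Aoah tumours, but over 8 such genes, chosen after their values were seen, the median excess in vector 3 was 0.723% of the Aoah tumour mean, against 10.8% for Aoah, and in vector 1 -0.150% against 3.57%. Immune cells as the source were argued against by the ratio of Aoah to the leukocyte gene Ptprc, 3.84 and 10.6 in this pair and at most 0.235 in the other 5 vector tumours, at least 16.4-fold apart. An exchange of labels between an Aoah and a vector tumour was argued against by the lowest Aoah tumour of either model, 5.18-fold above vector 3. Material of Luc Aoah tumours mixed into the sample would raise the same 8 genes and is argued against by the same values; tumour cells that took up the Aoah plasmid may account for the signal, which was not tested.

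Because Dlk1, Meg3 (-2.73), Rian (-2.24), Peg3 (-2.14) and H19, at 2941 TPM with Aoah against 11280.4 TPM with vector, were lower with Aoah in Luc, other imprinted growth genes were tested as a group. Of 14 measured genes without these, 6 fell and 1 rose in Luc (median -0.57, limma's fry p = 0.0128, camera p = 0.401 with an estimated correlation), among them Cdkn1c at -1.93, Grb10 at -1.42 and Igf2 at -1.35. The mean of the 14 differed by -0.59 between the groups, which missed 0.05 in an exact permutation test (p = 0.0571, n = 4 each). Imprinted growth genes may have fallen as a group in Luc by fry, but not by the permutation of tumours. In LucOS none passed and the question stays open (fry p = 0.740, exact permutation p of the mean = 0.5, n = 3 each).

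The falls of Reg3b, Reg3g, Socs3, A2m and Serpina3n raised the hypothesis that targets of interleukin-6 signalling through Stat3 were lower as a group. Of 25 other targets, 17 of them also in the fixed lists, 14 fell and none passed as higher in Luc (median -0.99, fry p = 0.0124, camera p = 0.301 with an estimated correlation). Junb stood at -1.94, Stat3 itself at -1.83 and Bcl3 at -1.79. Negative changes were seen in 22 of the 25, while Saa1 (0.95), Saa2 (0.89) and Hpx (0.28) had positive ones. The mean of the 25 differed by -0.97 (exact permutation p = 0.0286, n = 4 each), and lower signalling through this route may explain the falls in Luc. Members such as Lcn2, Lbp, Fga and Fgb are described above as falling, so these p-values are not independent of results already seen. In LucOS 1 fell and the group did not pass (fry p = 0.183, exact permutation p of the mean = 0.5, n = 3 each), which leaves it open.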
